A study of Mus musculus with 6 samples.

How the data were processed

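RNA from mouse splenic B cells was measured by poly A selected, strand-specific RNA sequencing in 6 libraries, 3 from cultures given DMSO (the solvent control) and 3 from cultures given Cpd10, which the labels describe as an inhibitor of the transcription factor FOXO1. Per the labels' protocols, naive B cells were sorted from 10 male mice, 3 months old and immunised with sheep red blood cells 9 days earlier, in 2 independent experiments, and were pooled before culture. The cells were cultured for 5 days with interleukin 4 (80 ng/ml) and an antibody against CD40 (5 µg/ml), and DMSO or 1 µM Cpd10 was present for the last 48 hours, from day 3 to day 5.

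The authors deposited whole-number read counts per gene, not normalised, for all 6 libraries in 1 table. The submitters' processing notes name STAR 2.7.10a, featureCounts 2.0.6 and DESeq2 and the mouse build GRCm38 (mm10). Whether the counting used the strand of the reads is not given in the sources used here, so overlapping genes on opposite strands, and near-identical gene copies, are uncertain. The table held 54838 gene identifiers, of which 54809 were found in GENCODE release M21, whose symbols and GRCm38 coordinates are used here, and 29 were not. The symbol Aldoa belongs to 2 identifiers, and both entered the gene list that holds it. The mitochondrially encoded genes were listed at 0 in every library and are not analysed here.

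Total counts ranged from 36873204 to 44859930 per library, so counting error is small for genes at 10 CPM (counts scaled by library size) or more, and the spread between libraries sets the precision. Replicate libraries of a group differed well beyond sampling noise: the chi-square per degree of freedom over genes ran from 12.3 (Cpd10 replicates B and C) to 176 (DMSO replicates B and C), so no library was treated as a duplicate. The labels do not say which cultures or animals the replicate letters stand for, so p-values measure only the spread between these libraries, which may be technical.

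The main comparison was made with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalisation, the filterByExpr filter (15136 genes tested), a quasi-likelihood fit with robust estimation and the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are Cpd10 minus DMSO, standard errors (SE) are the fold change divided by the square root of the F statistic, and CPM values use the normalised library sizes. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 39 lists that had at least 3 tested members, out of 43; the lists of mitochondrially encoded genes and of neutrophil, mast cell and basophil, and erythroid markers had fewer. Beside it stand camera with an estimated correlation and fry.

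The gene lists, the tests of genes and lists, the alternatives and the rule for naming genes were fixed before the data were examined. Some tests under Other observations were chosen after results were seen, as stated there. The rule names a fixed set of transcription factor, receptor and proliferation genes. It adds the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between the groups, leaving out clone names and immunoglobulin segments; 5 genes met the conditions for a fall. It also adds up to 4 tested members, those with the smallest p, of each list described. Genes named outside the rule are marked as chosen after their values were seen. Untested list members that are given for low or absent counts also lie outside the rule and are not marked one by one.

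One term was added after seeing the data. The libraries fell into 2 sets that crossed the groups, and the fit was repeated with the set as a term beside the group. The set is not in the labels. It was taken as the split of the 6 libraries into 3 and 3 with the most genes at 3 counts or fewer in 3 libraries and 50 or more in the other 3. A covariate picked from the same counts can lower the residual spread more than a known batch would, so p-values from this fit are exploratory.

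The procedure was tested on simulated data, in 10 simulations with 200 changed genes each (14597 to 14688 genes per simulation). Counts were drawn from the fitted means of these libraries, including the difference between the sets, with no group effect except in the changed genes. Dispersions were those of the fit with the set term, whose residual spread may be too low, so the recovery may be too high. Each gene was drawn independently, so correlation within lists beyond the set difference was not simulated. For the comparison of Cpd10 with DMSO, the fit with the group alone recovered 2.24% of genes changed 1.5-fold, 33.4% of those changed 2-fold and 58.0% of those changed 4-fold, and 0.161% of its calls were false. The fit with the set term, given the true sets, recovered 39.3%, 67.2% and 78.0%, and 13.1% of its calls were false (6.25% to 18.9% by simulation), above the nominal level. A list raised 2-fold in 1 further simulation was called by camera in both fits, and with an estimated correlation only in the fit with the set term (camera adjusted p = 0.399 without it, 0.00967 with it). At the preset correlation camera also called 3 other lists without the set term and 1 with it. Lists that hold some of the raised genes, such as the dark zone list, were not left out, so these are not counts of false calls. A list called at that correlation alone is still treated here as weak evidence.

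Alternatives fixed beforehand were other normalisations, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, the replicate letter as a block, leaving out immunoglobulin and mitochondrial genes, leaving out each library in turn, a test against a 1.5-fold change, a fit that was not robust, and an adjusted p under 0.01. DESeq2 was run without the filter, so its results differ from the main fit in both the tool and the genes tested. Its gene lists were tested with the pre-ranked form of camera on the DESeq2 test statistics. Sequence shared by neighbouring genes was searched with blastn 2.17.0.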

Results

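The data were gene counts from 6 libraries of cultured mouse B cells activated in vitro with interleukin 4 and an antibody against CD40, signals that stand in for help from T cells. Cultures received DMSO or the FOXO1 inhibitor Cpd10 (1 µM) for the last 48 hours, with 3 libraries in each group. The series title concerns T cell help and the plasticity of germinal centre B cells, and this comparison asks which transcripts of activated B cells differ when FOXO1 is inhibited. Libraries held 42798114, 36873204 and 40881235 counts in DMSO replicates A, B and C, and 44859930, 40822434 and 38110927 in Cpd10 replicates A, B and C.

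The libraries separated in a way that the treatment did not explain. Along the first principal component of log2 CPM (46.3% of the variance), DMSO A, DMSO C and Cpd10 A lay on one side and DMSO B, Cpd10 B and Cpd10 C on the other, called set 1 and set 2 here; the second (22.7%) separated DMSO from Cpd10. Ribosomal protein genes took 6.48%, 6.03% and 6.18% of the counts in the 3 libraries of set 1, and 10.5%, 10.9% and 9.79% in those of set 2. Immunoglobulin genes took 3.53%, 7.01% and 4.31% in set 1 and 2.79%, 2.60% and 2.60% in set 2. Across genes, DMSO C correlated more closely with Cpd10 A (Pearson r = 0.971) than with DMSO B (0.954); genes are not independent replicates. Each set held libraries of both groups, so the comparison below is given without the set, as fixed beforehand, and with it, as a term added after seeing the data.

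**Figure D1:**
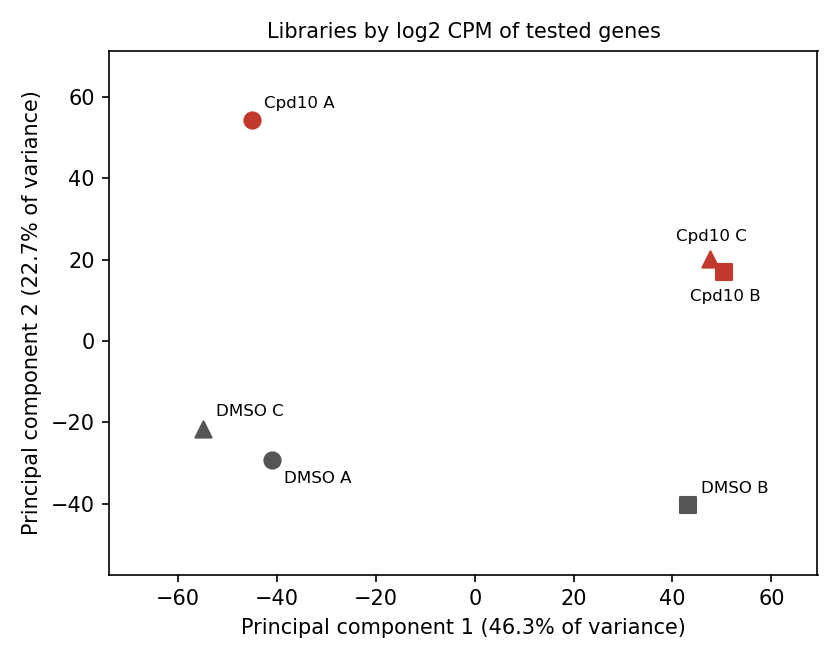
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, grey for DMSO and red for Cpd10, and the marker shape giving the replicate letter. Component 1 (46.3% of the variance) parts DMSO A, DMSO C and Cpd10 A from the other libraries, and component 2 (22.7%) parts the treatments.

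In cells given Cpd10, Ints6l, a paralogue of a subunit of the Integrator complex, rose from 59.2 ± 8.19 to 279 ± 25.2 CPM (mean ± SD, n = 3 per group). The E3 ubiquitin ligase gene March1, whose product lowers MHC class II at the cell surface, rose from 48.4 ± 9.01 to 181 ± 23.2 CPM. Ciita, the master transcriptional activator of MHC class II genes, fell from 372 ± 95.9 to 135 ± 12.2 CPM. Rgs1, a regulator of G protein signalling that restrains chemokine responses, fell from 19.6 ± 3.81 to 3.55 ± 0.601 CPM, and Fcmr, the Fc receptor for IgM, from 94.1 ± 18.5 to 36.7 ± 5.27 CPM. Bcl2l11, which encodes the pro-apoptotic protein BIM and is a known FOXO target, rose from 156 ± 3.40 to 294 ± 7.35 CPM.

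By edgeR's quasi-likelihood test, 56 of 15136 genes changed, of which 48 were higher and 8 lower in Cpd10, and 47 changed at least 2-fold. An unadjusted p under 0.05 was found for 1270 of the 15136, the background for such counts in the gene lists below. The 3 libraries of one group lay above the 3 of the other for all 56 called genes and for 14.6% of all tested genes, where chance gives 10%. Among called genes, the log2 fold change of Ints6l (chromosome X, 56454857 to 56507843, identifier ENSMUSG00000035967) was 2.23 (SE 0.13, edgeR adjusted p = 0.00426). That of March1 (chromosome 8, 65617900 to 66471637, ENSMUSG00000036469) was 1.90 (SE 0.17, edgeR adjusted p = 0.0125), and that of Ciita (chromosome 16, 10480059 to 10528418, ENSMUSG00000022504) was -1.46 (SE 0.20, adjusted p = 0.0355). Rgs1 (chromosome 1, 144242296 to 144249242, ENSMUSG00000026358) had a log2 fold change of -2.46 (SE 0.22, edgeR adjusted p = 0.0125), and Bcl2l11 (chromosome 2, 128126038 to 128162547, ENSMUSG00000027381) one of 0.91 (SE 0.084, adjusted p = 0.0125). Among called genes at a mean of 10 CPM or more, clone names left out, the largest fitted rise was that of the kinase gene Stk32b, from 0.0691 ± 0.0602 to 26.7 ± 9.51 CPM, a fold that rests on very few counts in DMSO. Nudt17, Serpinb6b, Serpinb9, Stk38l, Net1, Saraf and Timd2 also rose, by log2 fold changes of 4.13, 1.93, 1.92, 1.69, 1.66, 1.63 and 1.62. Itga6 and Mgat5 fell by 1.07 and 0.89 on the log2 scale. Serpinb9, Serpinb6b and Timd2 belong to gene families whose copies can share reads.

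**Figure D2:**
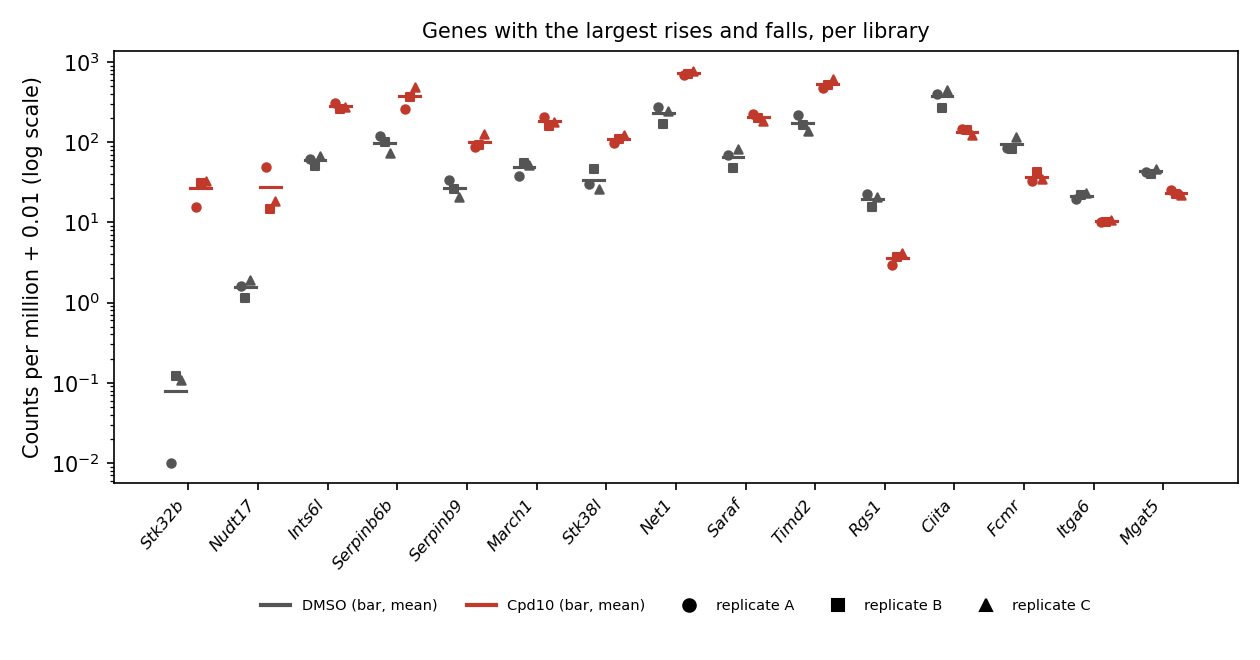
CPM (plus 0.01, log scale) of the 10 genes with the largest rise and the 5 with the largest fall, with 1 point per library, grey for DMSO and red for Cpd10, marker shapes for the replicate letters and bars for group means. For each gene the 3 Cpd10 libraries lie on one side of the 3 DMSO libraries.

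The number of called genes depended on single libraries. By edgeR it was 5 without DMSO A, 100 without DMSO B and 1 without DMSO C. It was 77 without Cpd10 A, 1 without Cpd10 B and 0 without Cpd10 C (843 genes at an unadjusted p under 0.05). All 56 genes kept their direction in each of these fits, which was close to fixed, since their groups did not overlap. Without DMSO B or without Cpd10 A, 1 group lies in 1 set alone, so these counts partly mix the set with the treatment. DESeq2, run without the filter (25082 genes with a p-value), called 356 genes on all 6 libraries, 205 higher and 151 lower. EdgeR without the filter called 194.

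With the library set as a term, Csf1, the gene of a macrophage growth factor, was lower in Cpd10 by a log2 fold change of -1.75 (SE 0.10), with means of 299 ± 64.2 CPM in DMSO and 108 ± 36.4 CPM in Cpd10 (n = 3 each). The integrin gene Itgb3 was higher (1.30, SE 0.092), as were Satb1, a chromatin organiser of lymphocytes (1.09, SE 0.097), and Birc2, an inhibitor of apoptosis (0.90, SE 0.084). Aire, the transcription factor of thymic self-antigen expression, was lower (-3.27, SE 0.23). These genes were chosen after their values were seen, from the 10 with the smallest p among genes at a mean of 10 CPM or more that were called with the set term alone, and their edgeR adjusted p in the fit without the set was 0.120, 0.288, 0.0649, 0.272 and 0.248. In all, edgeR called 599 genes with the set term, 351 higher and 248 lower, and 211 of them at least 2-fold, with 13.1% of calls false in simulated data that were given the true sets. The set was picked from these counts, so its calls are exploratory. Of the 56 genes, 55 were called again in the same direction; Serpinb6b was not (edgeR adjusted p = 0.103). The count with the set term was 130 without Cpd10 A, 225 without Cpd10 C, 343 without Cpd10 B and 907 without DMSO A. Without Cpd10 A, set 1 holds only DMSO libraries, so that comparison rests on set 2, where DMSO B is the only DMSO library.

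Transcripts of the FOXO family did not pass the test. Foxo1 was at 138 ± 16.5 CPM in DMSO and 118 ± 10.0 CPM in Cpd10 (n = 3 each; log2 fold change -0.22, SE 0.12, edgeR adjusted p = 0.711), and Foxo3 and Foxo4 had log2 fold changes of -0.15 and 0.37 (adjusted p = 0.913 and 0.584). Of 32 tested FOXO target genes, 1 rose (Bcl2l11), 0 fell and 31 did not pass, and 10 of the 32 had an unadjusted p under 0.05. DESeq2 called 3 of the 32 higher and 2 lower, limma-voom 1 higher, and edgeR adjusted over the list alone 4 higher and 5 lower. With the set term, edgeR called 2 higher (Bcl2l11 and Trib1) and 2 lower (Cxcr4, and Irs2, an insulin receptor substrate, named here after its value was seen; -0.59, adjusted p = 0.0117). Klf2, a regulator of lymphocyte trafficking, was at 75.5 ± 26.8 CPM in DMSO and 27.5 ± 5.10 CPM in Cpd10 (log2 fold change -1.46, edgeR adjusted p = 0.120), Trib1 had 1.22 (adjusted p = 0.0778, and 0.0290 with the set term), and the chemokine receptor gene Cxcr4 had -0.52 (adjusted p = 0.226, and 0.0282 with the set term). Il7r, the interleukin 7 receptor, was at 1.98 ± 2.13 and 33.7 ± 11.1 CPM (edgeR adjusted p = 0.260), and Ccr7, a homing receptor, at 124 ± 36.0 and 57.3 ± 16.9 CPM (adjusted p = 0.227). The list as a whole was not called (median log2 fold change -0.19, mean -0.096, camera adjusted p = 0.166, and 0.639 with an estimated correlation). Fry's directional test gave an adjusted p of 0.613, and its test for change in either direction 3.17e-04. The latter was not particular to this list, and gave 6.85e-06 for the BCL2 family list, which also holds Bcl2l11. Its values for lists of B cell states are given below, and not all of them passed.

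Among genes of B cell states, none of 24 naive follicular, 22 germinal centre, 24 light zone, 20 dark zone, 30 plasma cell or 38 MYC target genes passed edgeR's test over all genes. At an unadjusted p under 0.05 there were 7, 3, 5, 5, 3 and 1 such genes in these lists, DESeq2 called 5 naive follicular (2 higher, 3 lower), 2 germinal centre (1 and 1), 1 light zone (lower), 2 dark zone (lower), 2 plasma cell (1 and 1) and 0 MYC target genes, and limma-voom 0. Bcl6, the germinal centre regulator, had a log2 fold change of 0.18 (edgeR adjusted p = 0.930), Myc -0.69 (0.501), Prdm1, the plasma cell regulator, -0.89 (0.604), Irf4 0.39 (0.619), Bach2 -0.35 (0.931), Xbp1 0.13 (0.910), Pax5 -0.16 (0.850), S1pr1 -0.18 (0.954) and Mki67 0.0038 (0.998). With the set term, the germinal centre list had 1 gene higher (Ezh2, a histone methyltransferase, 0.63, edgeR adjusted p = 0.00800) and 2 lower, among them Gcsam, a signalling adaptor (-1.76, adjusted p = 0.0182). Gcsam was low, at a mean of 3.43 CPM in DMSO and 1.03 CPM in Cpd10. The dark zone list had 4 higher, among them Aurka (0.37, edgeR adjusted p = 0.0433), and 3 lower: Lmo4 (-0.66, adjusted p = 0.00687), Gcsam and Cxcr4. Irf4, in the light zone and plasma cell lists, was higher (0.49, SE 0.098, edgeR adjusted p = 0.0131). The naive follicular list had 2 higher and 1 lower, the light zone list 1 and 1, and the plasma cell and MYC target lists 1 higher and 0 lower each. Of 5 tested pluripotency genes, none passed edgeR's test, 2 had an unadjusted p under 0.05 and DESeq2 called 1, lower. Of those not tested, Nanog, Esrrb and Tbx3 had 0 counts in every library.

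The plasma cell list had a median log2 fold change of -0.25 and was called lower by camera (adjusted p = 0.0430; 0.825 with an estimated correlation, and 0.403 with the set term). Without DMSO C the median turned to 0.011 (camera adjusted p = 0.855). The lists of naive follicular, germinal centre, light zone, dark zone, MYC target and pluripotency genes were not called (camera adjusted p = 0.187, 0.851, 0.195, 0.858, 0.647 and 0.162). In the same order, fry's test for change in either direction gave adjusted p of 0.00943, 0.00823, 0.305, 0.00392, 0.760 and 0.0425. For the plasma cell list that test gave 0.398.

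Among antigen presentation genes Ciita fell, as given above. Of 24 tested, the other 23 did not pass. Of all 24, 11 had an unadjusted p under 0.05, and DESeq2 called 4, limma-voom 1 and edgeR adjusted over the list alone 8, all lower. H2-Ob, H2-Eb1 and H2-Ab1, components of the MHC class II pathway, had log2 fold changes of -0.76, -0.78 and -0.72 (edgeR adjusted p = 0.116, 0.130 and 0.211). With the set term these edgeR adjusted p were 0.0233, 0.0110 and 0.0124, and 6 members were lower. The list was called lower by camera (median -0.30, adjusted p = 1.46e-04), but not with an estimated correlation (adjusted p = 0.639). In the B lineage identity list, Fcmr fell and 29 of 30 members did not pass; 7 of the 30 had an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 1, all lower. Cd72 and Blk had -1.01 and -0.62 (edgeR adjusted p = 0.0659 and 0.0831, and 0.0193 and 0.00505 with the set term, where 5 members were lower and 1 higher). The list was called lower by camera (adjusted p = 0.00156), but not with an estimated correlation (0.636).

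Genes of the cell cycle, among them Rrm2 (ribonucleotide reductase) and Cdk1 (the mitotic kinase), did not pass without the set. None of 32 S phase and 36 G2/M phase genes passed edgeR's test, and DESeq2 and limma-voom called 0. An unadjusted p under 0.05 was found for 1 and 3 of them, beside 1270 of all 15136 tested genes. Both lists were called higher by camera (medians 0.15 and 0.18, adjusted p = 0.0253 and 0.00928), but not with an estimated correlation (adjusted p = 0.849 and 0.825). Once the set term was added, 10 S phase and 15 G2/M genes were higher and 0 lower, among them Rrm2 (0.55, edgeR adjusted p = 0.00197), Lig1 (0.51, 0.00678), Aurka (0.37, 0.0433) and Cdk1 (0.40, 0.0289). The list medians were then 0.29 and 0.28, with a camera adjusted p of 0.676 for both at an estimated correlation. Without Cpd10 A and without the set, the medians were -0.055 and -0.020.

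In all, camera called 19 of 39 lists, 5 higher and 14 lower, and 0 with an estimated correlation (lowest adjusted p = 0.636). At an estimated correlation without the set term, camera also missed the list raised 2-fold in the simulation (adjusted p = 0.399). Losing a call there thus cannot show that a list did not change. With the set term camera called 12, and 0 with an estimated correlation (lowest adjusted p = 0.676). Of the 12, 11 had been called in the same direction without it; the other was the p53 target list (median -0.26, camera adjusted p = 0.0219, and 0.940 without the set). Each median below is given without and then with the set term, and calls are those of camera at the preset correlation, which none of these lists kept at an estimated one. Of the other lists called higher, oxidative phosphorylation kept its call with the set term (0.18 and 0.10), and glycolysis (0.39 and 0.17, camera adjusted p = 0.0677 with the set term) and ribosomal protein genes (0.26 and -0.0082, 0.849) lost it. Of the other lists called lower, the call was kept by the unfolded protein response (-0.23 and -0.16), xenobiotic and oxidative stress (-0.31 and -0.38), immediate early (-0.41 and -0.50), fibroblast and endothelial (-1.34 and -1.23), integrated stress response (-0.12 and -0.20), and autophagy and lysosome lists (-0.15 and -0.16). It was lost by the immunoglobulin constant (-0.46 and -0.28), memory B cell (-0.35 and -0.46), PI3K pathway (-0.14 and -0.097; camera adjusted p = 0.0677 with the set term for each of these 3), chemokine and migration receptor (-0.24 and -0.11, 0.127) and NK cell lists (-0.78 and 0.040, 0.384). Fry's directional test called the fibroblast and endothelial list lower without the set term (adjusted p = 0.0448) and with it (0.0119), and the PI3K pathway list lower with it (0.00761). Without the set term no member of the lists in this paragraph passed edgeR's test over all genes, and counts at an unadjusted p under 0.05 ran from 0 (glycolysis) to 7 (integrated stress response). DESeq2 called 2 genes lower in each of the p53 target, immediate early, fibroblast and endothelial, integrated stress response, and chemokine and migration receptor lists, 1 in each of the xenobiotic and oxidative stress and NK cell lists, 2 lower and 1 higher in the memory B cell list and 0 in the others, and limma-voom 0. EdgeR called, with the set term, 3 lower and 1 higher in each of the memory B cell and chemokine and migration receptor lists. It called 3 lower in each of the xenobiotic and oxidative stress and autophagy and lysosome lists, 2 lower in each of the immediate early, fibroblast and endothelial, and PI3K pathway lists, and 1 lower in each of the p53 target, integrated stress response, NK cell, glycolysis and immunoglobulin constant lists. It called 1 ribosomal protein gene higher, and 0 genes of oxidative phosphorylation and the unfolded protein response. The remaining 20 lists had camera adjusted p from 0.0859 to 0.940.

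Markers of other cells differed in direction between and within lists, while the 4 tested fibroblast and endothelial markers were called lower as a list, as given above. Of these 4, Pdgfrb went the other way without the set term (log2 fold change 0.48, and -1.02 with it). Members of that list that were not tested reached at most 0.588 CPM, and Col3a1, Dcn and Pdgfra had 0 counts in every library. In the macrophage list, Cd68, a lysosomal protein, rose from 17.7 ± 3.36 to 48.6 ± 1.39 CPM (n = 3 each; edgeR adjusted p = 0.0168), while Adgre1 was at 18.5 ± 3.97 and 12.0 ± 2.83 CPM (log2 fold change -0.63, adjusted p = 0.529; -0.80 and 0.0252 with the set term). Lyz2 reached at most 0.244 CPM, and C1qa and C1qb had 0 counts in every library. The T cell marker Thy1 was abundant, at 350 ± 115 and 209 ± 52.5 CPM (edgeR adjusted p = 0.538; log2 fold change -0.46 and 0.0167 with the set term). Cd28 was at 14.1 and 9.33 CPM, but the T cell list members not tested, Cd3e among them, reached at most 0.759 CPM, and Themis and Icos had 0 counts. The dendritic cell markers Zbtb46, Bst2 and Flt3 were at 39.7, 27.6 and 23.8 CPM in DMSO and 41.5, 26.1 and 14.4 CPM in Cpd10, and did not pass with or without the set term. Dendritic cell list members not tested reached at most 0.262 CPM, and Clec9a and Clec10a had 0 counts in every library. Eomes (NK cells), Pecam1 and Fn1 (endothelial cells and fibroblasts) were lower with the set term (log2 fold changes of -2.87, -1.43 and -1.76, edgeR adjusted p = 0.00924, 0.0356 and 0.0123), and did not pass without it (0.0778, 0.130 and 0.277). Their means were 2.00, 13.4 and 3.81 CPM in DMSO and 0.288, 4.88 and 1.30 CPM in Cpd10. Hbb-bt, a haemoglobin gene of red cells, had 8, 8 and 0 counts in DMSO and 99, 119 and 91 in Cpd10 (edgeR adjusted p = 0.126, and 0.00687 with the set term), while Hba-a1 and Hba-a2 had 0 in every library.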

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

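The set term and its leave-one-out fits were chosen after seeing the data; the other alternatives were fixed beforehand. The 56 called genes kept their direction when any 1 library was left out, which was close to fixed because their groups did not overlap. Of them, 37 were called in 2 of those 6 fits, 12 in 1, 3 in 0, 3 in 3 and 1 (Ints6l) in 5. The count was 5 without DMSO A, 100 without DMSO B, 1 without DMSO C, 77 without Cpd10 A, 1 without Cpd10 B and 0 without Cpd10 C, where 843 genes had an unadjusted p under 0.05 by edgeR. Leaving out 1 library moved the count of changed genes between 0 and 100, genes higher between 0 and 66, genes lower between 0 and 37, 2-fold changes between 0 and 80, and called lists between 12 and 17. Each such fit has 3 libraries against 2, so part of a lower count comes from fewer samples. DMSO B is the only DMSO library of set 2, and Cpd10 A the only Cpd10 library of set 1. Without either, 1 group lies in 1 set alone, so the higher counts partly mix the set with the treatment. How much of the rise comes from this was not tested.

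DESeq2, run without the filter (25082 genes with a p-value), called 356 genes (205 higher, 151 lower, 241 at least 2-fold). EdgeR with no filter, on 25099 genes, gave 194 (124, 70, 118). The stricter filter gave 33 (28, 5, 27) on 8881 genes, so fewer genes were tested. A test against a 1.5-fold change left 7 (6, 1, 7), and an adjusted p under 0.01 left 2 (2, 0, 2), as stricter criteria must. The set term gave 599 (351 higher, 248 lower, 211 at least 2-fold). Without 1 library it gave 907 (466, 441, 260) without DMSO A, 437 (230, 207, 227) without DMSO B, 622 (372, 250, 200) without DMSO C, 130 (95, 35, 87) without Cpd10 A, 343 (210, 133, 159) without Cpd10 B and 225 (151, 74, 117) without Cpd10 C. Without DMSO B or Cpd10 A, 1 set holds a single group. The treatment comparison then rests on the other set, where 1 group has only 1 library. Under other scalings 50 to 59 genes were called, and the share of higher calls stayed within 84.0% to 86.4%.

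Deviations from group means correlated positively between libraries of the same set and negatively between sets. They correlated at 0.31 for letter A, 0.43 for B and -0.31 for C, and DMSO C went best with Cpd10 A (0.46). Letters A and B join libraries of the same set and letter C does not, so this cannot tell whether a letter marks a shared culture. The replicate block gave 49 genes (40 higher, 9 lower), 38 of them among the 56, and a plasma cell list median of -0.23 (camera adjusted p = 0.0823, in a range of 0.00396 to 0.825).

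Called lists numbered 19. They fell to 0 with an estimated correlation, to 1 with fry's directional test, to 12 with the set term and to 12 without DMSO A. The plasma cell median was -0.25 with an estimated correlation (adjusted p = 0.825) and with fry (0.613), -0.24 with no filter (0.0579), -0.23 without immunoglobulin and mitochondrial genes (0.0632) and -0.15 with the set term (0.403), over a range of adjusted p from 0.00396 to 0.825. Without 1 library it ran from -0.32 to 0.011 (0.00649 to 0.855), and the call was lost without DMSO C (where the median turned to 0.011), Cpd10 B (-0.22) and Cpd10 C (-0.21). The S phase median of 0.15 and the G2/M median of 0.18 lost their calls with an estimated correlation (0.849 and 0.825) and with fry (0.717 and 0.637). Over the alternatives with all libraries their adjusted p ran from 7.73e-10 to 0.849 and from 1.86e-10 to 0.825. Without 1 library they ran from -0.055 to 0.26 (3.49e-04 to 0.894) and from -0.020 to 0.26 (4.03e-04 to 0.895). Both turned negative without Cpd10 A (-0.055 and -0.020; adjusted p = 0.712 and 0.895) and were not called without DMSO B (0.014 and 0.095).

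Camera on the DESeq2 statistics, over genes without the filter, added calls for the naive follicular (-0.16, adjusted p = 0.0221, range 0.0221 to 0.749) and light zone lists (-0.041, 0.0155, range 0.0155 to 0.823). It also called the pluripotency list (-0.23, 0.0285, range 0.0285 to 0.636). Without 1 library the naive follicular median ran from -0.28 to -0.0090 (0.0307 to 0.721) and the MYC target median from -0.079 to 0.14 (0.0426 to 0.941), each called without DMSO B (-0.28 and 0.14). The ribosomal protein median turned to -0.0082 with the set term (0.849). The median log2 fold change of NK cell markers, -0.78, turned to 0.040 with the set term (adjusted p = 0.384, range 0.0147 to 0.636). Without 1 library it ran from -2.66 without Cpd10 A to 0.022 without DMSO C (0.0152 to 0.166), and the call was lost without DMSO A (-0.88), DMSO C (0.022), Cpd10 B (-0.017) and Cpd10 C (-0.43). The cause of these changes was not tested. In the fit without DMSO B the DMSO group lies in set 1 alone, which partly mixes the set with the treatment. Of 17 named genes that were called, the set term, the upper-quartile scaling and the stricter filter each lost 1, limma-voom and no filter 2 each, and the block 6. The RLE and library-size scalings, DESeq2, leaving out immunoglobulin and mitochondrial genes and the fit that was not robust lost 0.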

Other observations

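The tests of the library sets on the 56 genes, of heavy chain V segments and of splits of the 6 libraries without the set term were chosen after the results were seen; those of GC content and length, of neighbouring genes and of splits with the set term were written before. Of 10 splits of the 6 libraries into 3 and 3, 2 called at least 56 genes: the real one and the split into the 2 sets, which called 2107 and points to a structure of the samples. With the set term, 1 of 9 possible splits called as many genes, the real one with 599, and the highest of the others called 0. Both numbers of splits are too small for a share under 0.05. Of the 56 genes, 55 were called again with the set as a term. For all 56 the libraries of the groups did not overlap, while the sets cross the groups. The result was thus close to fixed and is no separate test of the set difference as a source.

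The 2 sets of libraries were picked as the split with the most genes at 3 counts or fewer in 1 set and 50 or more in the other, so the 9 such genes, against 1 for the treatment and 0 for each of the 8 other splits, describe the choice and do not test it. Among them, Sycp1, a meiotic gene, had 0, 2 and 0 counts in set 1 and 136, 128 and 166 in set 2, and Rnf150 had 151, 92 and 88 in set 1 and 0 in each library of set 2; both were chosen after their values were seen. A smooth trend with GC content and length was small beside these differences: removing it from each library moved tested genes by a median of 0.0850 log2 units, and 9 of 9 genes stayed above 3 log2 units (smallest 4.90), which was close to fixed by how they were chosen. A candidate explanation is a difference in the genetic background of the mice behind the 2 sets, although the labels say that cells were pooled before culture and link no library to mice or to a sort experiment: 119 heavy chain V segments, leaving out those that helped define the sets, differed between the sets by a median of 1.95 log2 units, against at most 0.413 in matched draws of coding genes and 0.894 in any other split. Other heavy chain V segments were among the 9 genes that defined the sets, so this comparison partly restates how the split was picked. For 106 kappa V segments the excess was far smaller (0.856, against at most 0.346 and 0.671). Different antibody repertoires of the cells in the 2 sets, which would also give such differences, stay open.

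Genes higher in Cpd10 with the set term lay beside each other more often than chance placement gives: 39 neighbouring pairs within 200 kb among 351 genes, against a median of 7 and at most 20 in 10000 random draws (permutation p = 0.0001, the smallest the draws can give). Lower genes also did so, with 10 pairs among 248 genes against a median of 3 and at most 13 (permutation p = 0.0020). Several pairs lay near Sp140 and Sp110 on chromosome 1, among them A530032D15Rik and A530040E14Rik, which start at 85083069 and 85105946 and had log2 fold changes of 2.25 and 0.97, and Armcx6 and Armcx3 lay together on chromosome X (3.17 and 1.27); these were chosen after their values were seen. Reads shared between the members of a pair are argued against as the main source, since 3 of the 39 pairs aligned over at least 100 bases at 95% identity or more. Copies outside each pair were not searched, so reads shared with them, as in the cluster near Sp140 and Sp110, stay open. Shared regulation of neighbours by the treatment, transcription running from one gene into the next, and a different mix of mouse genotypes in the treated cultures may each place changed genes together; none of these was tested.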
